A study of Danio rerio with 16 samples.

How the data were processed

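RNA from sorted cells of the ventricular apex of adult zebrafish aged 3 to 9 months, carrying both kdrl:mCherry and postnb:citrine, was sequenced in 16 libraries. Per the labels' protocols, the apexes of 3 to 5 hearts were pooled per sample and dissociated with trypsin, the cells were sorted by fluorescence, and between 0.2 and 0.6 ng of total RNA was amplified with the Ovation Single Cell RNA-Seq kit. The labels also name a TruSeq kit without saying which libraries it made. Reads were single and 60 bases long. Low input and amplification add spread between libraries and between genes. The double-negative sort is all cells without either reporter, so it is a mixture.

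The authors deposited 1 table of TPM (the share of each gene's transcripts, scaled to a fixed total) per gene ID and library. The file names no unit: the values have 2 decimals, every library sums to 1000000 within rounding over 31388 gene IDs, and the low values share no step that a whole read would give. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt, RSEM 1.2.25 and the genome build Zv9 were used. The annotation release, the read filters and the version of cutadapt are not given in the sources used here. RSEM divides reads shared by similar transcripts among them by estimate, so values of near-identical genes are uncertain, and 94 IDs with a mean of at least 1 TPM fell into 26 sets with identical values. The depth of the libraries is unknown, since TPM keeps no counts, and no interval or detection floor is given. TPM are shares of a total, so an abundant transcript lowers all others in its library.

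All 16 columns were matched to samples by name. Of the 31388 IDs, 25925 had a symbol in the name table used and 5463 had none, and 11759 symbols were human-style names in capitals, some of them shared by several IDs. Where a named symbol belongs to several tested IDs, the ID is printed at its first mention. Groups were uninjured mCherry-positive (3 libraries), mCherry-positive at 7 dpi (4), citrine-positive at 7 dpi (3) and double-negative at 7 dpi (6). Each library is a separate sort of pooled hearts. The labels give each library a number under the tag pool. That libraries of different sorts with the same number came from the same pooled hearts is a reading of that tag, which the labels do not spell out.

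The design fixed before the data were examined foresaw counts or normalized values. As the table held TPM, the test named for normalized values was used: limma 3.58.1 in R 4.3.3, with the trend option, on log2(TPM + 1), in a model with 1 mean per group over all 16 libraries. Fold changes are on that scale, which understates the change of low genes. The 19039 IDs with at least 1 TPM in at least 3 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The filter, the pseudocount of 1 and their alternatives stand in place of those planned for counts. No batch or pool term was in the model. The overlap tests were also run in R. Summary tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

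Fixed before the data were examined, 28 gene lists of cell types, pathways and stress were tested with camera (two-sided, preset inter-gene correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation. Of 749 fixed members 270 matched a symbol exactly, 201 in another case, 209 after dropping a paralog letter and 69 not at all, giving 715 IDs. A match after dropping the letter can take in more than 1 paralog. Neither mpeg1.1 nor hbba1 of the fixed markers had a match. The lists overlap, as for dll4 (Notch, angiogenic) and il1b (neutrophil, injury cytokine).

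The rule for named genes, fixed before the data were examined, took the reporter genes and sort markers in every comparison. It took the 10 largest rises and 10 largest falls in the first and second comparison, and 5 each in the others, among called genes with a usable name, no overlap between groups and a mean of at least 20 TPM in the higher group. It also took up to 4 members of each list by adjusted p. This last part was shortened after values were seen: to the first 2 members of lists called with both correlations and the first 1 of other called lists, and in the first comparison to 2 of each called list and every such member past the threshold. Genes named outside the rule are said to be so.

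The overlap of gene calls was tested with Fisher's exact test, and the correlation of fold changes over all splits of the 7 mCherry-positive libraries. Alternatives planned for each result were median-of-ratios scaling, no filter, a filter at 5 TPM, and pseudocounts of 0.1 and 5. Also planned were a fit on the compared groups alone, a fold change minimum and leaving out each library. The pool of hearts as a block was run only where the compared groups shared pool numbers. For citrine-positive against double-negative cells, the mean of double-negative and mCherry-positive libraries as the rest was planned too. Added after the data were seen were array weights, removal of the 20 most abundant IDs, quantile normalization, a term for the set of pools (9 and 10 against 2 to 8) and fits within each set, and for the overlap a setting with no pool number in both comparisons, 1 without mCherry-positive pool 9 and 1 with median-of-ratios scaling.

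Deviations from group means had a median correlation of 0.163 for 9 pairs of libraries of the same pool, 0.106 for 18 pairs of other pools in the same set and -0.107 for 27 pairs across sets. It was over 0.1 in 6 of the 9 pairs of the same pool, so the values alone do not establish the pairing. The block was not run for injured against uninjured hearts, since no pool number held both and no block was possible there. That comparison is therefore untested for pool effects by a block. For the other comparisons the block results stand beside a result where they changed its call.

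The tests were checked on simulated log2 values for 19039 genes, with 50 genes changed at each size. For 7 dpi against uninjured, 8%, 62%, 82% and 98% of genes changed by 1, 2, 3 and 4 log2 units were recovered. For citrine-positive against double-negative cells the shares were 4%, 48%, 82% and 90%, against mCherry-positive cells 6%, 48%, 86% and 98%, and for mCherry-positive against double-negative cells 2%, 62%, 96% and 92%. In the same order, 4.58%, 5.08%, 4.03% and 7.35% of calls were false. A shifted list was recovered in all 4 comparisons and 0 of 27 other lists were called by camera. Noise was drawn independently for each gene, without pool effects, and the changed genes were taken from the better expressed ones. Real lists were correlated, with an estimate of 0.449 for fibrillar matrix genes. The simulation therefore cannot show how often correlated lists are called falsely.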

Results

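RNA was measured by sequencing in cells sorted from the apex of the zebrafish ventricle. The adult fish carried the reporters kdrl:mCherry, which marks endothelial and endocardial cells, and postnb:citrine, driven from a gene for periostin, a matrix protein of activated fibroblasts. Hearts were left uninjured or cryoinjured, that is, damaged locally by cold, and taken at 7 days post injury (7 dpi). The 16 libraries were 3 of mCherry-positive cells from uninjured hearts, 4 of mCherry-positive cells at 7 dpi, 3 of citrine-positive cells at 7 dpi, and 6 of cells negative for both reporters at 7 dpi, called double-negative here. Values were TPM, the share of each transcript scaled to a fixed total per library, so the number of reads behind each library is unknown and no counting interval could be given. Between 12111 and 16854 gene IDs per library reached 1 TPM, and the 20 most abundant IDs held between 26.1% and 62.8% of the TPM in mCherry-positive libraries at 7 dpi and between 61.3% and 65.1% in citrine-positive libraries. Group levels are given as mean ± SD, and log2 fold changes of log2(TPM + 1) as estimate ± SE. Values in parentheses after a gene are its log2 fold change, and its adjusted p where given. Adjusted p values are from limma for genes and from camera for gene lists, with Benjamini-Hochberg adjustment.

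The reporter gene kdrl was highest in mCherry-positive libraries. Both POSTN IDs had their highest mean in citrine-positive libraries. Neither passed against double-negative cells in the fit over all 16 libraries (adjusted p = 0.112 and 0.566 by limma). The first, ENSDARG00000104267, still lay at 714.6 to 1532 TPM in citrine-positive and 202.3 to 426.4 TPM in double-negative libraries. It passed when these 2 groups were fitted alone. The endothelial receptor gene kdrl (ENSDARG00000105215) had 387 ± 94.4 TPM in uninjured mCherry-positive libraries (n = 3), 214 ± 51.0 TPM in those at 7 dpi (n = 4), 1.1 ± 0.55 TPM in citrine-positive libraries (n = 3) and 36.9 ± 13.5 TPM in double-negative libraries (n = 6). The periostin gene POSTN (ENSDARG00000104267) had 1059 ± 423 TPM in citrine-positive libraries, 302 ± 98.5 TPM in double-negative libraries and 16.8 ± 15.09 TPM in mCherry-positive libraries at 7 dpi. Another ID with the same symbol, POSTN (ENSDARG00000043806), had 206 ± 172 TPM in citrine-positive and 136 ± 33.1 TPM in uninjured mCherry-positive libraries. In mCherry-positive libraries at 7 dpi it had 156.5 ± 167.9 TPM, with up to 407 in 1 library against at most 381.8 in citrine-positive ones. The names used here do not tell which of both IDs drove the reporter. The double-negative libraries also held 73.8 ± 34.2 TPM of cdh5 (ENSDARG00000075549), which encodes VE-cadherin of endothelial junctions, and 36.6 ± 11.07 TPM of TCF21 (ENSDARG00000036869), a transcription factor of epicardium and fibroblasts.

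**Figure D1:**
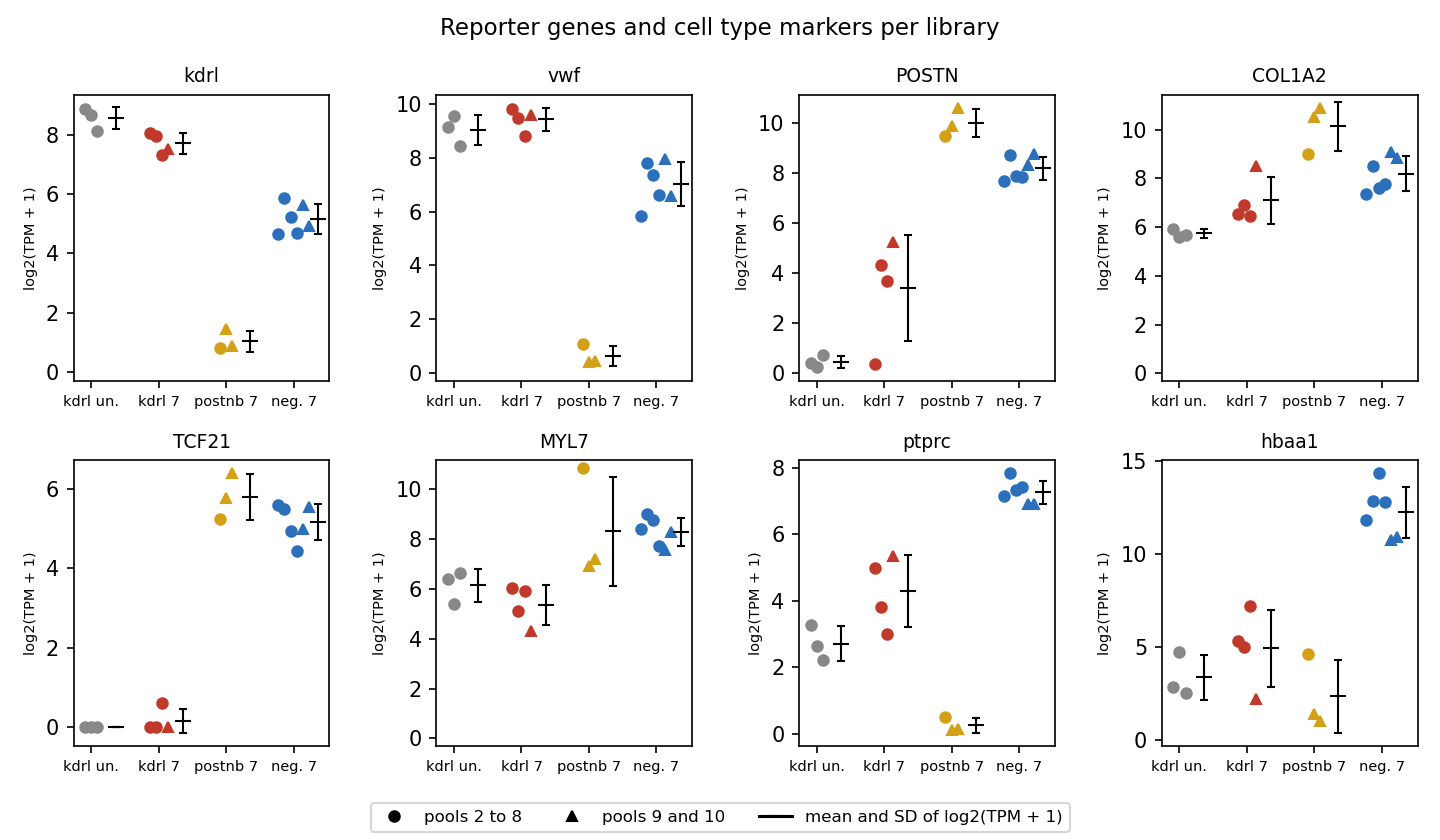
Level of 8 genes in each library, as log2(TPM + 1) on the vertical axis, with the 4 groups on the horizontal axis (kdrl un., uninjured mCherry-positive, then mCherry-positive, citrine-positive and double-negative at 7 dpi); circles are pools 2 to 8, triangles pools 9 and 10, and bars the mean ± SD of log2(TPM + 1). POSTN is ENSDARG00000104267, and kdrl and vwf were lowest in the citrine-positive libraries, where kdrl averaged 1.1 TPM.

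Principal component 1 held 24.8% of the variance and component 2 held 16.7%, and the 3 sorts lay apart on them. Within sorts, pools 9 and 10 differed from pools 2 to 8: the IDs si:dkeyp-3b12.11 and si:dkeyp-3b12.8 took between 25.7% and 35.8% of the TPM in all 5 libraries of pools 9 and 10 and at most 2.09% in the other 11. All uninjured libraries came from pools 2 to 4, so the comparison with uninjured hearts was also made within pools 2 to 8. No pool number held both uninjured and injured hearts. Injury therefore cannot be told apart from differences between pools, within pools 2 to 8 as well.

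**Figure D2:**
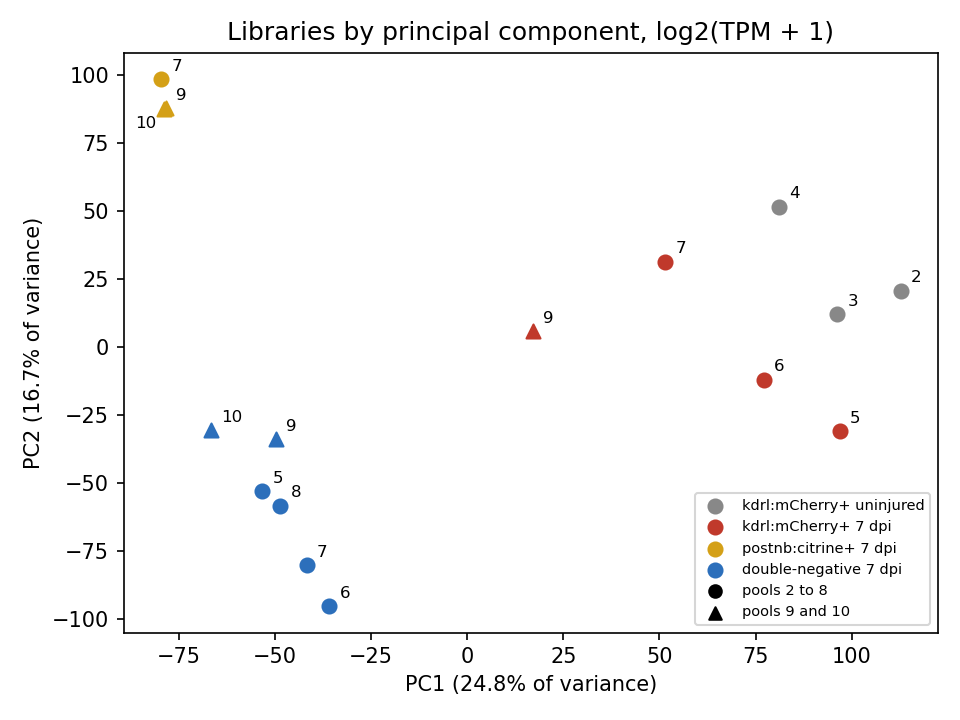
The 16 libraries on the first and second principal component of log2(TPM + 1), in arbitrary units, with each component's share of the variance on its axis; colour is the group, shape the set of pools, and the number the pool of hearts. The citrine-positive and double-negative libraries lie apart from each other and from the mCherry-positive libraries, of which the 7 dpi library of pool 9 lies nearest to the others.

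The first comparison asked how mCherry-positive cells of injured hearts differed from those of uninjured hearts. At 7 dpi few genes passed, among them 1 of 22 fibrillar matrix, 2 of 26 matricellular, 1 of 30 collagen processing and 2 of 30 macrophage genes, all higher. These 4 lists passed upward with the preset correlation, each with adjusted p = 0.758 with an estimated correlation. FN1 (ENSDARG00000019815), which encodes the provisional matrix protein fibronectin, rose from 1.73 ± 1.29 to 45.6 ± 37.0 TPM (n = 3 and 4, 3.92 ± 0.49, adjusted p = 5.29e-04), and MFAP4 (ENSDARG00000038681), a name that in zebrafish marks macrophages, from 0.05 ± 0.09 to 19.2 ± 10.2 TPM (4.12 ± 0.52, adjusted p = 5.29e-04). Each symbol has a more abundant ID that was not called. FN1 (ENSDARG00000006526) averaged 48.2 TPM uninjured and 82.4 at 7 dpi, and MFAP4 (ENSDARG00000090783) 54.9 and 135.1. Of 19039 genes tested, limma called 132, with 80 higher and 52 lower (60.6% higher), and 2189 had an unadjusted p under 0.05. That balance turned without uninjured pool 4, with 56 higher and 77 lower (42.1% higher), and with a pseudocount of 5, with 32 higher and 54 lower. The fall in 17 of the 52 lower IDs was 1 measurement, since these unnamed IDs had identical values in every library. The calls depended on the estimate of spread shared with the other groups: fitted on these 7 libraries alone, limma called 0 genes, with 1306 at an unadjusted p under 0.05.

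The largest rises by the rule for named genes were in NPC2 (ENSDARG00000096979), which encodes a lysosomal cholesterol carrier (4.81 ± 0.40, adjusted p = 5.66e-06), and F13A1, the catalytic subunit of coagulation factor XIII (ENSDARG00000045453, 4.14 ± 0.66, adjusted p = 0.00555). They also included crlf1a, a cytokine receptor-like factor (4.01 ± 0.88, adjusted p = 0.0399), tnfrsf11a, which encodes the receptor RANK (3.85 ± 0.70), and GFPT2 of the hexosamine pathway (3.83 ± 0.68). The tetraspanin gene tspan34b (3.74 ± 0.79), the collagen crosslinking enzyme LOXL2 (ENSDARG00000044074, 3.71 ± 0.59) and the sphingosine-1-phosphate receptor S1PR1 (3.60 ± 0.53) rose. NET1 reached 155 ± 111 TPM against 8.44 ± 2.43 TPM (3.70 ± 0.68). BRD9, a chromatin remodelling subunit, fell from 25 ± 7.54 to 2.31 ± 1.72 TPM (-3.16 ± 0.58, adjusted p = 0.0105). CALCRL, the receptor component for adrenomedullin, fell from 151 ± 59.7 to 36.5 ± 12.5 TPM (-2.01 ± 0.46, adjusted p = 0.0478). TLNRD1 (-2.71 ± 0.59), SPTSSA (-2.63 ± 0.54) and DNAJB5 (-2.37 ± 0.47) fell as well. So did cyp2ad6 (-2.12 ± 0.42), RND3 (ENSDARG00000076799, -1.66 ± 0.38) and TRIM8 (ENSDARG00000090512, -1.66 ± 0.36), and these 8 were all the lower genes that met the rule. Some folds moved by over 1.5 times without 1 library. Without uninjured pool 2, F13A1 was at 4.83, tspan34b at 4.62 and DNAJB5 at -1.77 (adjusted p = 0.113), without uninjured pool 3 crlf1a was at 4.69, and without uninjured pool 4 tnfrsf11a was at 3.25 (0.0557). Without pool 9 at 7 dpi crlf1a was at 4.76 and tspan34b at 4.40.

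Genes of fibrillar matrix rose as a list, with COL5A1 at 197 ± 62.8 TPM against 45.8 ± 9.81 (2.05 ± 0.40, adjusted p = 0.0168). Of 22 members 1 rose (6 rose adjusted over the list alone), with adjusted p = 4.02e-05, and adjusted p = 0.758 with an estimated correlation. Its members col11a1b (2.14 ± 0.51, adjusted p = 0.0612), POSTN (ENSDARG00000104267, 2.94 ± 0.73, adjusted p = 0.0824) and COL1A2 (1.35 ± 0.54, adjusted p = 0.330) did not pass. Matricellular and provisional matrix genes rose, with FN1 and THBS1 (2.37 ± 0.52, adjusted p = 0.0399) called. Of 26 members 2 rose (8 rose and 1 fell adjusted over the list alone), with adjusted p = 5.27e-04, and adjusted p = 0.758 with an estimated correlation. Collagen processing genes rose, with LOXL2 called, while FKBP10 (ENSDARG00000045129), listed at 0 in all uninjured libraries, was not. Of 30 members 1 rose (1 rose adjusted over the list alone), with adjusted p = 0.0196, and adjusted p = 0.758 with an estimated correlation. Mural and smooth muscle genes rose, with MYLK (ENSDARG00000034801), the myosin light chain kinase, called (3.18 ± 0.71, adjusted p = 0.0414) and rgs5b not (1.64 ± 0.64, adjusted p = 0.319). Of 17 members 1 rose (1 rose adjusted over the list alone), with adjusted p = 0.00200, and adjusted p = 0.758 with an estimated correlation. Outside the called lists, the basement membrane genes NID2 (2.69 ± 0.43, adjusted p = 0.00555) and LAMB2 (2.57 ± 0.52, adjusted p = 0.0220) rose. The transglutaminase TGM2 (ENSDARG00000074094, 3.05 ± 0.64, adjusted p = 0.0270) and the chemokine ccl35.1 (2.53 ± 0.56, adjusted p = 0.0399) rose too. The basement membrane list did not pass, and its median of -0.09 and mean of 0.17 differed in sign. The log2 fold change of ccl35.1 was 3.32 without uninjured pool 2 and 1.82 without pool 4 (adjusted p = 0.155), and that of MYLK 3.89 without pool 7 at 7 dpi and 2.495 without pool 9 (0.0683). Without uninjured pool 4 rgs5b was at 0.82.

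Macrophage genes had the lowest p of the lists, and apoeb, an apolipoprotein gene of macrophages, rose from 3.33 ± 1.66 to 51.7 ± 19.5 TPM (3.59 ± 0.48, adjusted p = 0.00110). Of 30 members 2 rose (7 rose adjusted over the list alone), with adjusted p = 9.19e-08, and adjusted p = 0.758 with an estimated correlation. Immediate early and dissociation stress genes passed downward as a list, but not without pool 9 at 7 dpi (adjusted p = 0.109). Of 37 members 0 passed (2 fell adjusted over the list alone), with adjusted p = 5.41e-04, and adjusted p = 0.758 with an estimated correlation. Its members BTG2, with 472 ± 86.9 against 1814 ± 466 TPM (-1.93 ± 0.50, adjusted p = 0.0988), and JUNB (ENSDARG00000104773, -1.74 ± 0.46, adjusted p = 0.107) missed the threshold over all genes. Of the same list the heat shock member hsp70.1, named after its values were seen, had 7009 ± 1847 TPM in pools 5 to 7 at 7 dpi, 61.8 in pool 9 and 5459 ± 921 in uninjured libraries. No list call held with an estimated correlation. The reporter and marker genes kdrl (-0.85 ± 0.37, adjusted p = 0.380), cdh5 (-0.32 ± 0.43, adjusted p = 0.832) and NFATC1 (-0.55 ± 0.41, adjusted p = 0.658) did not pass. Neither did MYL7 (-0.81 ± 0.70, adjusted p = 0.714), TNNT2 (ENSDARG00000020610, 0.53 ± 0.81, adjusted p = 0.861) or POSTN (ENSDARG00000043806, -0.28 ± 0.84, adjusted p = 0.949), nor TCF21, listed at 0 in all uninjured libraries. TNNT2 was at 1.19 without uninjured pool 3, and that POSTN ID at -0.91 without pool 9 at 7 dpi.

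**Figure D3:**
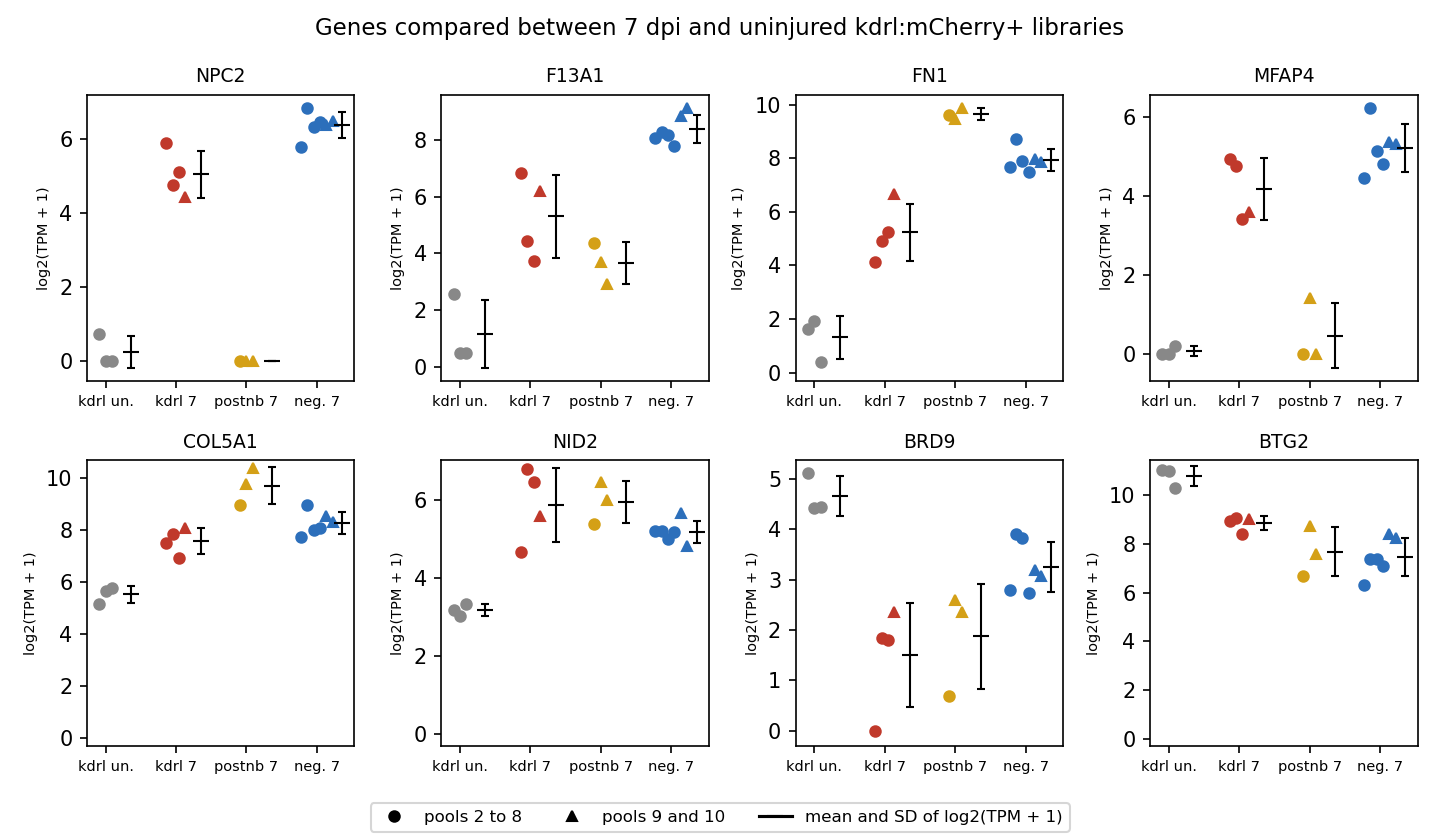
Level of 8 genes in each library, as log2(TPM + 1) on the vertical axis, with groups, symbols and bars (mean ± SD of log2 values) as in the plot of reporter genes and markers. NPC2, F13A1, FN1, MFAP4, COL5A1 and NID2 were called higher and BRD9 lower at 7 dpi in mCherry-positive libraries, while BTG2 missed the threshold with an adjusted p of 0.0988.

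Of the 27 named genes called in this comparison, 10 (NPC2, F13A1, FN1, GFPT2, LOXL2, NET1, S1PR1, NID2, MFAP4 and apoeb) kept their call whichever library was left out. Without 1 of the 3 uninjured libraries 13 (pool 2), 17 (pool 3) and 15 (pool 4) kept it, and without 1 of the 4 libraries at 7 dpi 19 (pool 5), 15 (pool 6), 23 (pool 7) and 21 (pool 9), with adjusted p between 0.0501 and 0.204 for the lost calls. The number of called genes was 83 without uninjured pool 2 and 205 without pool 9 at 7 dpi. Within pools 2 to 8 it was 115, of which 74 were shared with the fit over all pools, and 13 of the 27 named genes kept their call. POSTN (ENSDARG00000104267) was called without pool 5 at 7 dpi (3.96, adjusted p = 1.95e-04) and col11a1b without pool 7 (2.48, adjusted p = 0.0206). Without pool 9 at 7 dpi that POSTN ID was lower (2.33, adjusted p = 0.131). Groups did not overlap for 6.92% of genes, against 5.71% by chance, and the share of higher calls was 71.3% after median-of-ratios scaling. With that scaling TLNRD1 lost its call (adjusted p = 0.0538), and JUNB (0.0376), col11a1b (0.0318), TGF-beta and BMP genes (0.0338) and EMT transcription factors (0.0494) gained one. Without the uninjured library of pool 2 the collagen processing list had adjusted p = 0.0856 and without pool 6 at 7 dpi 0.108. Leaving out a library brought in the lists coronary and lymphatic vessel (adjusted p = 0.0205), injury cytokine and JAK-STAT (0.00831) and TGF-beta and BMP (0.0372) without uninjured pool 2, and injury cytokine (0.0239) without pool 9. It brought in endocardial and mitochondrially encoded (both 0.0412) without uninjured pool 4, and endothelial and EMT transcription factors (both 0.0224) without pool 5.

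The second comparison set citrine-positive cells against the double-negative cells of injured hearts. Citrine-positive cells had more RNA of fibroblast and fibrillar matrix genes and less of erythroid, macrophage and endothelial genes, with either correlation. TNC (ENSDARG00000021948), which encodes the matricellular protein tenascin C, had 47.9 ± 14.2 against 3.55 ± 0.60 TPM (n = 3 and 6, 3.40 ± 0.41, adjusted p = 1.42e-05), and ptprc, the leukocyte antigen CD45, had 0.20 ± 0.20 against 157 ± 40.7 TPM (-7.01 ± 0.44, adjusted p = 1.41e-08). Of 19039 genes, limma called 1876, with 338 higher and 1538 lower, and groups did not overlap for 16.6% of genes against 2.38% by chance.

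The largest rises were in RSPO1, which encodes the Wnt agonist R-spondin (4.53 ± 0.59, adjusted p = 3.22e-05), angptl7 (4.11 ± 0.60, adjusted p = 1.07e-04) and THBS4 (ENSDARG00000102777, 4.05 ± 0.59, adjusted p = 1.15e-04). They were followed by thbs2b (3.89 ± 0.60), GYG1 (ENSDARG00000059391, 3.65 ± 0.68), the laminin gene lamc3 (3.63 ± 0.56) and abi3bpb (3.36 ± 0.70). The elastin gene elnb had 463 ± 252 against 44.0 ± 32.7 TPM (3.55 ± 1.02, adjusted p = 0.0312). The rule also took itih3a.2, which had 37.6 ± 53.7 TPM in citrine-positive libraries and was listed at 0 in all double-negative ones. The largest falls were in globin genes, with HBE1 (ENSDARG00000089087) at 31.2 ± 50.3 against 23318 ± 27159 TPM (-10.44 ± 1.26, adjusted p = 1.47e-05). HBE1 (ENSDARG00000097238, -9.94 ± 1.12), HBE1 (ENSDARG00000069734, -8.47 ± 0.82), hbaa1 (-9.90 ± 0.96) and hbaa2 (-8.56 ± 0.96) fell with it. Near-identical globin copies can share reads, so their single values are uncertain. The heme synthesis gene alas2 (-7.04 ± 0.76), fcer1gl (-7.71 ± 0.57), gja13.2 (-7.52 ± 0.57) and nt5c2l1 (-7.15 ± 0.93) also fell. Without citrine-positive pool 9 the log2 fold changes were lower for RSPO1 (3.35), THBS4 (3.03), GYG1 (2.69), lamc3 (2.55) and abi3bpb (2.54), and without pool 10 they were higher for RSPO1 (5.35), THBS4 (4.67), GYG1 (4.61) and lamc3 (4.42). HBE1 (ENSDARG00000089087) was at -12.07, -9.45 and -9.81 without citrine-positive pool 7, 9 or 10, HBE1 (ENSDARG00000097238) at -10.96 and -9.11 without pool 7 or 10, and hbaa1 at -11.03 and -9.23.

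With either correlation, fibroblast and fibrillar matrix genes were higher, with COL1A2, a chain of collagen I, at 1300.4 ± 718 against 324 ± 157 TPM (1.95 ± 0.50, adjusted p = 0.0163), COL11A1 (2.43 ± 0.40) and col11a1b (2.60 ± 0.47). Of 22 members 16 rose (18 rose adjusted over the list alone), with adjusted p = 7.58e-17, and adjusted p = 0.0449 with an estimated correlation. Matrix proteases and inhibitors passed upward with members of both directions, the membrane protease MMP15 rising (ENSDARG00000013072, 2.29 ± 0.37, adjusted p = 3.58e-04) and mmp13a falling (-5.29 ± 0.83, adjusted p = 2.38e-04). Of 28 members 11 rose and 3 fell (14 rose and 4 fell adjusted over the list alone), with adjusted p = 3.14e-06, and adjusted p = 0.0403 with an estimated correlation. Retinoic acid genes were higher, including CYP26B1, which degrades retinoic acid (2.73 ± 0.56, adjusted p = 0.00281), and rbp5 (2.22 ± 0.53, adjusted p = 0.00949). Of 22 members 5 rose (7 rose adjusted over the list alone), with adjusted p = 5.27e-05, and adjusted p = 0.0413 with an estimated correlation. Without citrine-positive pool 7 mmp13a was at -6.41, and CYP26B1 was at 1.91 without pool 9 and 3.32 without pool 10.

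The other higher lists lost their call with an estimated correlation. Matricellular and provisional matrix genes, TNC and THBS4 among them, were higher. Of 26 members 7 rose (12 rose adjusted over the list alone), with adjusted p = 3.11e-11, and adjusted p = 0.0549 with an estimated correlation. Basement membrane genes, such as lamc3, were higher. Of 19 members 2 rose (7 rose adjusted over the list alone), with adjusted p = 1.79e-09, and adjusted p = 0.0647 with an estimated correlation. Collagen processing genes were higher, with LOXL3 (ENSDARG00000039563, 1.25 ± 0.32, adjusted p = 0.0144). Of 30 members 3 rose (3 rose adjusted over the list alone), with adjusted p = 1.66e-08, and adjusted p = 0.0647 with an estimated correlation. Epicardial genes were higher, with the keratin gene krt4 (3.14 ± 0.48, adjusted p = 1.72e-04). Of 23 members 6 rose and 1 fell (7 rose and 1 fell adjusted over the list alone), with adjusted p = 4.16e-06, and adjusted p = 0.0681 with an estimated correlation. Mural and smooth muscle genes passed upward, although the called members, smtnb among them (-2.48 ± 0.50, adjusted p = 0.00268), were lower. Of 17 members 2 fell (2 fell adjusted over the list alone), with adjusted p = 0.0223, and adjusted p = 0.288 with an estimated correlation. EMT transcription factors and mesenchymal genes passed upward, with FOXC1 lower (-2.24 ± 0.40, adjusted p = 9.06e-04). Of 22 members 3 rose and 1 fell (3 rose and 1 fell adjusted over the list alone), with adjusted p = 2.59e-04, and adjusted p = 0.111 with an estimated correlation. Schwann and neural genes passed with no called member, plp1b at 1.02 ± 0.37, adjusted p = 0.0962. Of 7 members 0 passed (0 passed adjusted over the list alone), with adjusted p = 0.0441, and adjusted p = 0.0960 with an estimated correlation. TGF-beta and BMP genes passed upward, with BMP10 lower (-3.92 ± 0.35, adjusted p = 5.63e-07). Of 39 members 1 rose and 2 fell (1 rose and 2 fell adjusted over the list alone), with adjusted p = 0.0408, and adjusted p = 0.476 with an estimated correlation. Without citrine-positive pool 9 krt4 was at 2.44.

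Endothelial, macrophage, neutrophil, erythroid and thrombocyte genes were lower with either correlation. Among endothelial genes cdh5 (-5.30 ± 0.40), kdrl (-4.13 ± 0.34) and vwf, von Willebrand factor (-6.40 ± 0.43), fell. Of 26 members 19 fell (22 fell adjusted over the list alone), with adjusted p = 1.92e-20, and adjusted p = 0.0334 with an estimated correlation. Macrophage genes fell, with ptprc and laptm5 (-6.16 ± 0.43). Of 30 members 26 fell (29 fell adjusted over the list alone), with adjusted p = 1.54e-34, and adjusted p = 0.0194 with an estimated correlation. Neutrophil genes fell, with il1b (-6.34 ± 0.68) and NCF1 (-6.22 ± 0.78). Of 10 members 8 fell (9 fell adjusted over the list alone), with adjusted p = 5.11e-10, and adjusted p = 0.0194 with an estimated correlation. Erythroid genes fell, with SLC4A1, the red cell anion exchanger (ENSDARG00000012881, -6.62 ± 0.57). Of 16 members 13 fell (15 fell adjusted over the list alone), with adjusted p = 7.58e-17, and adjusted p = 0.0321 with an estimated correlation. Thrombocyte genes fell, with FGL2 (-5.15 ± 0.43) and itga2b, listed at 0 in all citrine-positive libraries against 18.9 ± 8.81 TPM. Of 12 members 8 fell (9 fell adjusted over the list alone), with adjusted p = 7.69e-07, and adjusted p = 0.0311 with an estimated correlation.

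With the preset correlation alone, coronary and lymphatic vessel, lymphocyte, injury cytokine and Notch genes were lower. Of coronary and lymphatic vessel genes CXCR4 fell (ENSDARG00000041959, -6.17 ± 0.65). Of 13 members 6 fell (7 fell adjusted over the list alone), with adjusted p = 3.14e-04, and adjusted p = 0.0759 with an estimated correlation. Lymphocyte genes fell, with CCR9 (-6.92 ± 0.63). Of 16 members 5 fell (9 fell adjusted over the list alone), with adjusted p = 3.07e-06, and adjusted p = 0.0681 with an estimated correlation. Injury cytokine genes fell, with ccl35.1 (-6.58 ± 0.52). Of 28 members 1 rose and 12 fell (2 rose and 15 fell adjusted over the list alone), with adjusted p = 4.05e-06, and adjusted p = 0.148 with an estimated correlation. Notch genes fell, with the ligand dll4 (-4.51 ± 0.47). Of 20 members 7 fell (2 rose and 9 fell adjusted over the list alone), with adjusted p = 0.00629, and adjusted p = 0.237 with an estimated correlation. POSTN (ENSDARG00000104267) did not pass (1.8 ± 0.68, adjusted p = 0.112) although all 3 citrine-positive libraries lay above the 6 double-negative ones. POSTN (ENSDARG00000043806, 0.91 ± 0.78, adjusted p = 0.566), TCF21 (0.64 ± 0.39, adjusted p = 0.380) and NFATC1 (0.24 ± 0.38, adjusted p = 0.795) did not pass either. This second POSTN ID was at 1.84 without citrine-positive pool 7 and at 0.205 without pool 10. MYL7 (0.02 ± 0.65, adjusted p = 0.991) and TNNT2 (-0.11 ± 0.75, adjusted p = 0.961) did not pass, with MYL7 at 1831 TPM in citrine-positive pool 7 and 120.2 and 146 in pools 9 and 10, against 189.9 to 507.6 in double-negative libraries. Without citrine-positive pool 7 the log2 fold changes were -1.24 for MYL7 (adjusted p = 0.152) and -1.34 for TNNT2 (0.298), and without pool 9 they were 0.72 and 0.53.

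Median-of-ratios scaling moved the median log2 fold change of all genes from -0.23 to -0.03 and gave 2453 calls, with 891 higher and 1562 lower, a share of higher calls of 36.3% against 18.0%. Against the mean of double-negative and mCherry-positive libraries limma called 2332 genes, 1390 of them among the 1876, with 765 higher and 1567 lower (32.8% higher), and POSTN (ENSDARG00000104267, adjusted p = 1.47e-04), TCF21 (8.57e-06) and plp1b (0.0102) passed upward. Within pools 2 to 8, with 1 citrine-positive library (pool 7) assumed to vary like the other groups, limma called 896 genes and 35 of the 45 named calls were kept, and within pools 9 and 10 it called 803 genes and 30 were kept. With median-of-ratios scaling Schwann and neural genes lost their call (adjusted p = 0.0639) and plp1b gained one (0.0207). POSTN (ENSDARG00000104267) passed after median-of-ratios scaling (adjusted p = 0.0452) and on the libraries of these 2 groups alone (0.00641). Without the citrine-positive library of pool 9 elnb, COL1A2 and LOXL3 lost their call (adjusted p = 0.145, 0.0894 and 0.097), as they did without that of pool 10 (0.107, 0.122 and 0.0906), and rbp5 lost it without that of pool 7 (0.0623). The gene elnb also lost it without the double-negative library of pool 5 (0.066), 8 (0.0553) or 10 (0.0524). With the pool of hearts as a block, LOXL3 (adjusted p = 0.0991) and the Notch list (0.0753) lost their call and the cardiomyocyte list gained one (0.00619). Schwann and neural genes lost their call without the citrine-positive library of pool 9 (0.0594) or 10 (0.0645) or the double-negative library of pool 7 (0.0771) or 9 (0.0551), and TGF-beta and BMP genes without citrine-positive pool 7 (0.119) or double-negative pool 9 (0.0528) or 10 (0.076). The cardiomyocyte list, not called over all libraries with a median of 0.08, was higher without citrine-positive pool 9 (median 0.73), pool 10 (0.70) or double-negative pool 5 (0.17) and lower without citrine-positive pool 7 (-1.07). Without that library glycolysis (median -1.49) and mitochondrially encoded genes (-0.97) were also called lower.

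The third comparison set citrine-positive against mCherry-positive cells at 7 dpi. Fibroblast and matricellular genes were higher in citrine-positive cells and endothelial genes were lower, with either correlation. The transferrin gene tfa had 849 ± 255 against 4.65 ± 7.86 TPM (n = 3 and 4, 8.20 ± 0.74, adjusted p = 3.54e-07), the matrix gene DPT, dermatopontin, had 547 ± 305 against 1.30 ± 1.33 TPM (7.89 ± 0.49, adjusted p = 3.95e-09), and vwf had 0.59 ± 0.44 against 716 ± 193 TPM (-8.81 ± 0.46, adjusted p = 9.05e-10). Of 19039 genes, limma called 2268, with 922 higher and 1346 lower. Of the higher IDs, 17 unnamed ones had identical values in every library and are 1 measurement. Groups did not overlap for 18.0% of genes against 5.71% by chance. Without mCherry-positive pool 7 tfa was at 9.08.

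Other large rises were hapln1a, a hyaluronan link protein gene (6.99 ± 0.60), vmo1a (6.63 ± 0.38) and POSTN (ENSDARG00000104267, 6.59 ± 0.73). Other large falls were SPOCK3 (-8.95 ± 0.48), the aquaporin gene AQP8 (-8.61 ± 0.41), cdh5 (-7.56 ± 0.43), the endothelial adhesion gene sele (-7.22 ± 0.44) and kdrl (-6.68 ± 0.37). The markers TCF21 (5.66 ± 0.42) and COL1A2 (3.05 ± 0.54) rose. MYL7, a cardiac myosin light chain (2.98 ± 0.70, adjusted p = 0.00747), and TNNT2, cardiac troponin T (2.54 ± 0.81, adjusted p = 0.0481), rose too. In citrine-positive pool 7 they were 13.8 and 12.8 times the mean of the other 2 citrine-positive libraries, and without pool 7 their log2 fold changes were 1.72 (adjusted p = 0.0408) and 1.31 (0.309), against 3.68 and 3.18 without pool 9. NFATC1 (-0.62 ± 0.41, adjusted p = 0.390) and POSTN (ENSDARG00000043806, 0.38 ± 0.84, adjusted p = 0.837) did not pass. That POSTN ID was at 1.31 without citrine-positive pool 7 and at -0.33 without pool 10. Without citrine-positive pool 7 hapln1a was at 7.86, and POSTN (ENSDARG00000104267) was at 5.58 without mCherry-positive pool 5 and 7.20 without pool 9.

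The following lists passed with either correlation. Endothelial genes fell. Of 26 members 22 fell (23 fell adjusted over the list alone), with adjusted p = 6.52e-31, and adjusted p = 0.0304 with an estimated correlation. Fibroblast and fibrillar matrix genes rose, with COL12A1 (ENSDARG00000019601, 6.20 ± 0.49) and LUM (5.64 ± 0.51). Of 22 members 17 rose (19 rose adjusted over the list alone), with adjusted p = 4.13e-22, and adjusted p = 0.0338 with an estimated correlation. Matricellular genes rose, with TNC (5.34 ± 0.44). Of 26 members 15 rose and 1 fell (17 rose and 1 fell adjusted over the list alone), with adjusted p = 5.26e-16, and adjusted p = 0.0338 with an estimated correlation. Matrix proteases and inhibitors rose, with MMP2 (4.15 ± 0.42) and ADAMTS8 (ENSDARG00000058252, 3.92 ± 0.43). Of 28 members 15 rose and 3 fell (15 rose and 3 fell adjusted over the list alone), with adjusted p = 1.02e-08, and adjusted p = 0.0304 with an estimated correlation. Schwann and neural genes rose, with plp1b at 2.93 ± 1.44 against 0.10 ± 0.19 TPM (1.8 ± 0.40, adjusted p = 0.00463), while SNAP25, listed at 0 in all mCherry-positive libraries at 7 dpi, did not pass. Of 7 members 1 rose (3 rose adjusted over the list alone), with adjusted p = 7.94e-04, and adjusted p = 0.0338 with an estimated correlation.

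The other higher lists passed with the preset correlation alone. Epicardial genes rose, with CXCL12 (5.69 ± 0.40). Of 23 members 10 rose and 3 fell (11 rose and 5 fell adjusted over the list alone), with adjusted p = 7.87e-05, and adjusted p = 0.124 with an estimated correlation. Basement membrane genes rose, with col18a1a (4.79 ± 0.50). Of 19 members 9 rose and 1 fell (12 rose and 2 fell adjusted over the list alone), with adjusted p = 5.37e-07, and adjusted p = 0.124 with an estimated correlation. Collagen processing genes rose, with pcolcea (5.95 ± 0.61). Of 30 members 7 rose (8 rose and 1 fell adjusted over the list alone), with adjusted p = 7.87e-05, and adjusted p = 0.176 with an estimated correlation. Retinoic acid genes rose, with rbp5 (5.46 ± 0.57). Of 22 members 8 rose and 2 fell (10 rose and 2 fell adjusted over the list alone), with adjusted p = 2.48e-04, and adjusted p = 0.0674 with an estimated correlation. Mural and smooth muscle genes rose, with smtnb lower (-4.53 ± 0.54). Of 17 members 6 rose and 2 fell (7 rose and 3 fell adjusted over the list alone), with adjusted p = 5.07e-04, and adjusted p = 0.138 with an estimated correlation. EMT transcription factors and mesenchymal genes rose, with FOXC1 lower (-4.67 ± 0.43). Of 22 members 8 rose and 2 fell (10 rose and 3 fell adjusted over the list alone), with adjusted p = 7.56e-05, and adjusted p = 0.124 with an estimated correlation. Mitochondrially encoded genes passed upward, mt-nd4l having 0.59 ± 0.41, adjusted p = 0.418. Of 13 members 0 passed (0 passed adjusted over the list alone), with adjusted p = 0.0427, and adjusted p = 0.669 with an estimated correlation. Cardiomyocyte genes rose, while myoglobin, mb, fell to 450.3 ± 479.9 against 6270.2 ± 1684 TPM (-4.28 ± 0.54, adjusted p = 1.86e-05). Of 30 members 15 rose and 2 fell (18 rose and 2 fell adjusted over the list alone), with adjusted p = 2.72e-08, and adjusted p = 0.200 with an estimated correlation. Without citrine-positive pool 7 mb was at -5.13.

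The other lower lists likewise passed with the preset correlation alone. Macrophage genes fell, with laptm5 (-4.28 ± 0.47). Of 30 members 22 fell (26 fell adjusted over the list alone), with adjusted p = 1.25e-16, and adjusted p = 0.0531 with an estimated correlation. Endocardial genes fell, SPOCK3 among them. Of 16 members 1 rose and 8 fell (1 rose and 8 fell adjusted over the list alone), with adjusted p = 7.56e-05, and adjusted p = 0.141 with an estimated correlation. Coronary and lymphatic vessel genes fell, with stab1 (-4.67 ± 0.46). Of 13 members 5 fell (7 fell adjusted over the list alone), with adjusted p = 6.33e-04, and adjusted p = 0.124 with an estimated correlation. Notch genes fell, with dll4 (-7.16 ± 0.51). Of 20 members 2 rose and 10 fell (2 rose and 12 fell adjusted over the list alone), with adjusted p = 1.08e-04, and adjusted p = 0.124 with an estimated correlation. Immediate early genes fell, with MYC (ENSDARG00000007241, -2.52 ± 0.44). Of 37 members 2 rose and 15 fell (2 rose and 15 fell adjusted over the list alone), with adjusted p = 7.87e-05, and adjusted p = 0.200 with an estimated correlation. Injury cytokine genes fell, with ccl35.1 (-5.12 ± 0.56). Of 28 members 1 rose and 6 fell (1 rose and 8 fell adjusted over the list alone), with adjusted p = 0.00519, and adjusted p = 0.413 with an estimated correlation.

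Median-of-ratios scaling moved the median of all genes from -0.19 to 0.13 and the share of higher calls from 40.7% to 61.8%, with 2505 calls, and mt-nd4l (adjusted p = 0.0333) and the neutrophil list (0.0197) gained a call. With the pool of hearts as a block limma called 1444 genes. TNNT2 (adjusted p = 0.0813) and plp1b (0.0649) lost their call, and the cell cycle list gained one (0.0436). Fitted on the 2 groups alone it called 1082 genes, without MYL7 (0.146) and TNNT2 (0.256), within pools 2 to 8, with 1 citrine-positive library, it called 1510, and within pools 9 and 10, with 1 mCherry-positive library, it called 418, each lone library being assumed to vary like the other groups. TNNT2 also lost its call without mCherry-positive pool 5 (0.144), 6 (0.0671) or 7 (0.104) or citrine-positive pool 7 (0.309). Mitochondrially encoded genes lost theirs without mCherry-positive pool 6 (0.0723), 7 (0.134) or 9 (0.0508) or citrine-positive pool 7 (0.843). Without citrine-positive pool 7, SNAP25 (0.0118) and the lists neutrophil (0.0453) and glycolysis (0.00378) were called. In that library 18 of 19 abundant cardiomyocyte genes lay above both other citrine-positive libraries.

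The fourth comparison set mCherry-positive against double-negative cells at 7 dpi and measured how well the sort divided them. Thrombocyte genes were lower with either correlation. With the preset one alone endothelial genes were higher and fibroblast and cardiomyocyte genes lower (adjusted p = 0.0745, 0.226 and 0.313 with an estimated correlation). The VEGF receptor gene flt1 had 203 ± 93.4 against 24.1 ± 10.5 TPM (n = 4 and 6, 2.94 ± 0.43, adjusted p = 2.32e-04) and DPT had 1.30 ± 1.33 against 318 ± 139 TPM (-7.15 ± 0.41, adjusted p = 5.21e-09). Of 19039 genes, limma called 2083, with 773 higher and 1310 lower, and groups did not overlap for 10.2% of genes against 0.952% by chance.

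The largest rises were in ALPL (3.27 ± 0.47), lnc.30 (3.04 ± 0.73), limch1b (3.03 ± 0.51), flt1 and wnk3 (2.88 ± 0.42). The markers kdrl (2.55 ± 0.31) and cdh5 (2.25 ± 0.36) rose. The largest falls were in hbaa2 (-8.19 ± 0.88), HBE1 (ENSDARG00000097238, -7.58 ± 1.02), HBE1 (ENSDARG00000089087, -7.48 ± 1.15), hbaa1 (-7.32 ± 0.88) and DPT. TCF21 (-5.02 ± 0.36), POSTN (ENSDARG00000104267, -4.79 ± 0.62), MYL7 (-2.96 ± 0.59, adjusted p = 0.00292) and TNNT2 (-2.65 ± 0.69, adjusted p = 0.0161) fell. COL1A2 (-1.10 ± 0.46, adjusted p = 0.145), NFATC1 (0.85 ± 0.35, adjusted p = 0.136) and POSTN (ENSDARG00000043806, 0.54 ± 0.71, adjusted p = 0.709) did not pass. The last of these was at -0.09 without mCherry-positive pool 9. Without mCherry-positive pool 7, hbaa2 was at -9.27, HBE1 (ENSDARG00000097238) at -8.30, HBE1 (ENSDARG00000089087) at -8.25 and hbaa1 at -8.09. Without pool 9 the last 3 were at -6.82, -6.16 and -6.41, and POSTN (ENSDARG00000104267) was at -5.40 without pool 9 and -3.78 without pool 5.

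Endothelial, endocardial, Notch, TGF-beta and BMP, and immediate early genes were higher, with the preset correlation alone. Endothelial genes rose. Of 26 members 20 rose (21 rose adjusted over the list alone), with adjusted p = 8.39e-18, and adjusted p = 0.0745 with an estimated correlation. Endocardial genes rose, with NOTCH1 (ENSDARG00000052094, 2.42 ± 0.28). Of 16 members 9 rose and 1 fell (10 rose and 1 fell adjusted over the list alone), with adjusted p = 1.61e-06, and adjusted p = 0.149 with an estimated correlation. Notch genes rose, NOTCH1 among them. Of 20 members 8 rose and 2 fell (9 rose and 3 fell adjusted over the list alone), with adjusted p = 0.00335, and adjusted p = 0.251 with an estimated correlation. TGF-beta and BMP genes rose, with BMP10 (2.40 ± 0.32). Of 39 members 6 rose and 2 fell (6 rose and 2 fell adjusted over the list alone), with adjusted p = 5.71e-04, and adjusted p = 0.251 with an estimated correlation. Immediate early genes rose, with MYC (2.25 ± 0.37). Of 37 members 10 rose and 1 fell (13 rose and 2 fell adjusted over the list alone), with adjusted p = 1.19e-06, and adjusted p = 0.170 with an estimated correlation.

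Thrombocyte genes were lower with either correlation, and erythroid, macrophage, neutrophil and lymphocyte genes with the preset one alone. Thrombocyte genes fell, with itga2b (-3.61 ± 0.44) and GP1BB (-3.49 ± 0.47). Of 12 members 7 fell (9 fell adjusted over the list alone), with adjusted p = 1.78e-08, and adjusted p = 0.0337 with an estimated correlation. Erythroid genes fell, with SLC4A1 (-6.20 ± 0.52). Of 16 members 12 fell (13 fell adjusted over the list alone), with adjusted p = 2.53e-15, and adjusted p = 0.0745 with an estimated correlation. Macrophage genes fell, with ptprc (-2.97 ± 0.40). Of 30 members 1 rose and 15 fell (1 rose and 21 fell adjusted over the list alone), with adjusted p = 3.90e-09, and adjusted p = 0.154 with an estimated correlation. Neutrophil genes fell, with MMP9 (-4.69 ± 0.60). Of 10 members 6 fell (8 fell adjusted over the list alone), with adjusted p = 6.65e-06, and adjusted p = 0.0745 with an estimated correlation. Lymphocyte genes fell, with nkl.2 (-5.55 ± 0.51). Of 16 members 5 fell (12 fell adjusted over the list alone), with adjusted p = 1.86e-06, and adjusted p = 0.149 with an estimated correlation.

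Lists of fibrillar matrix, matricellular, matrix protease, mural, cardiomyocyte, mitochondrially encoded, and Schwann and neural genes were lower with the preset correlation alone, while basement membrane (adjusted p = 0.623) and collagen processing genes (0.613) did not pass. Fibroblast and fibrillar matrix genes fell, with COL12A1 (-4.28 ± 0.41). Of 22 members 7 fell (10 fell adjusted over the list alone), with adjusted p = 7.10e-07, and adjusted p = 0.226 with an estimated correlation. Matricellular genes fell, with hapln1a (-5.90 ± 0.50). Of 26 members 2 rose and 11 fell (3 rose and 13 fell adjusted over the list alone), with adjusted p = 1.15e-05, and adjusted p = 0.226 with an estimated correlation. Matrix proteases and inhibitors fell, MMP9 among them. Of 28 members 1 rose and 11 fell (2 rose and 14 fell adjusted over the list alone), with adjusted p = 5.71e-04, and adjusted p = 0.149 with an estimated correlation. Mural genes fell, with CSPG4 (-2.79 ± 0.41). Of 17 members 1 rose and 5 fell (2 rose and 5 fell adjusted over the list alone), with adjusted p = 0.0399, and adjusted p = 0.372 with an estimated correlation. Cardiomyocyte genes fell, with TNNI1 (ENSDARG00000052708, -4.19 ± 0.65), while mb, chosen after its values were seen, rose (2.51 ± 0.46, adjusted p = 0.00136). Of 30 members 1 rose and 14 fell (3 rose and 19 fell adjusted over the list alone), with adjusted p = 1.61e-06, and adjusted p = 0.313 with an estimated correlation. Mitochondrially encoded genes fell, with mt-atp8 (-1.29 ± 0.39, adjusted p = 0.0377). Of 13 members 2 fell (13 fell adjusted over the list alone), with adjusted p = 4.86e-05, and adjusted p = 0.313 with an estimated correlation. Schwann and neural genes fell, with mbpb (-1.64 ± 0.48, adjusted p = 0.0312). Of 7 members 1 fell (1 fell adjusted over the list alone), with adjusted p = 0.0446, and adjusted p = 0.154 with an estimated correlation.

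Median-of-ratios scaling moved the median of all genes from -0.10 to -0.25, with 2516 calls. With that scaling the Schwann and neural list lost its call (adjusted p = 0.0670) and COL1A2 gained one (0.0485). Within pools 9 and 10, with 1 mCherry-positive library assumed to vary like the other groups, limma called 2 genes. With the pool of hearts as a block mt-atp8 (adjusted p = 0.0595) and the Schwann and neural list (0.0622) lost their call and the injury cytokine list gained one (0.0446). TNNT2 lost its call without mCherry-positive pool 5 (0.0726) or 7 (0.0602). The gene mbpb lost it without mCherry-positive pool 5 (0.0684) or 7 (0.118) or double-negative pool 5 (0.0504), 6 (0.0527), 9 (0.0638) or 10 (0.0687), and mt-atp8 without mCherry-positive pool 6 (0.133) or 7 (0.128) or double-negative pool 5 (0.062), 6 (0.0718), 9 (0.0511) or 10 (0.0757). The Schwann and neural list lost it without mCherry-positive pool 5 (0.0538), 6 (0.0575), 7 (0.059) or 9 (0.0778) or double-negative pool 5 (0.0671), 9 (0.0535) or 10 (0.0731), and the mural list without mCherry-positive pool 5 (0.156) or 7 (0.059) or double-negative pool 6 (0.0722). Calls were gained by NFATC1 without mCherry-positive pool 7 (0.037), by COL1A2 without pool 9 (0.0238), and by the injury cytokine list without mCherry-positive pool 5 (0.00853) or double-negative pool 9 (0.0305) or 10 (0.0466).

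**Figure D4:**
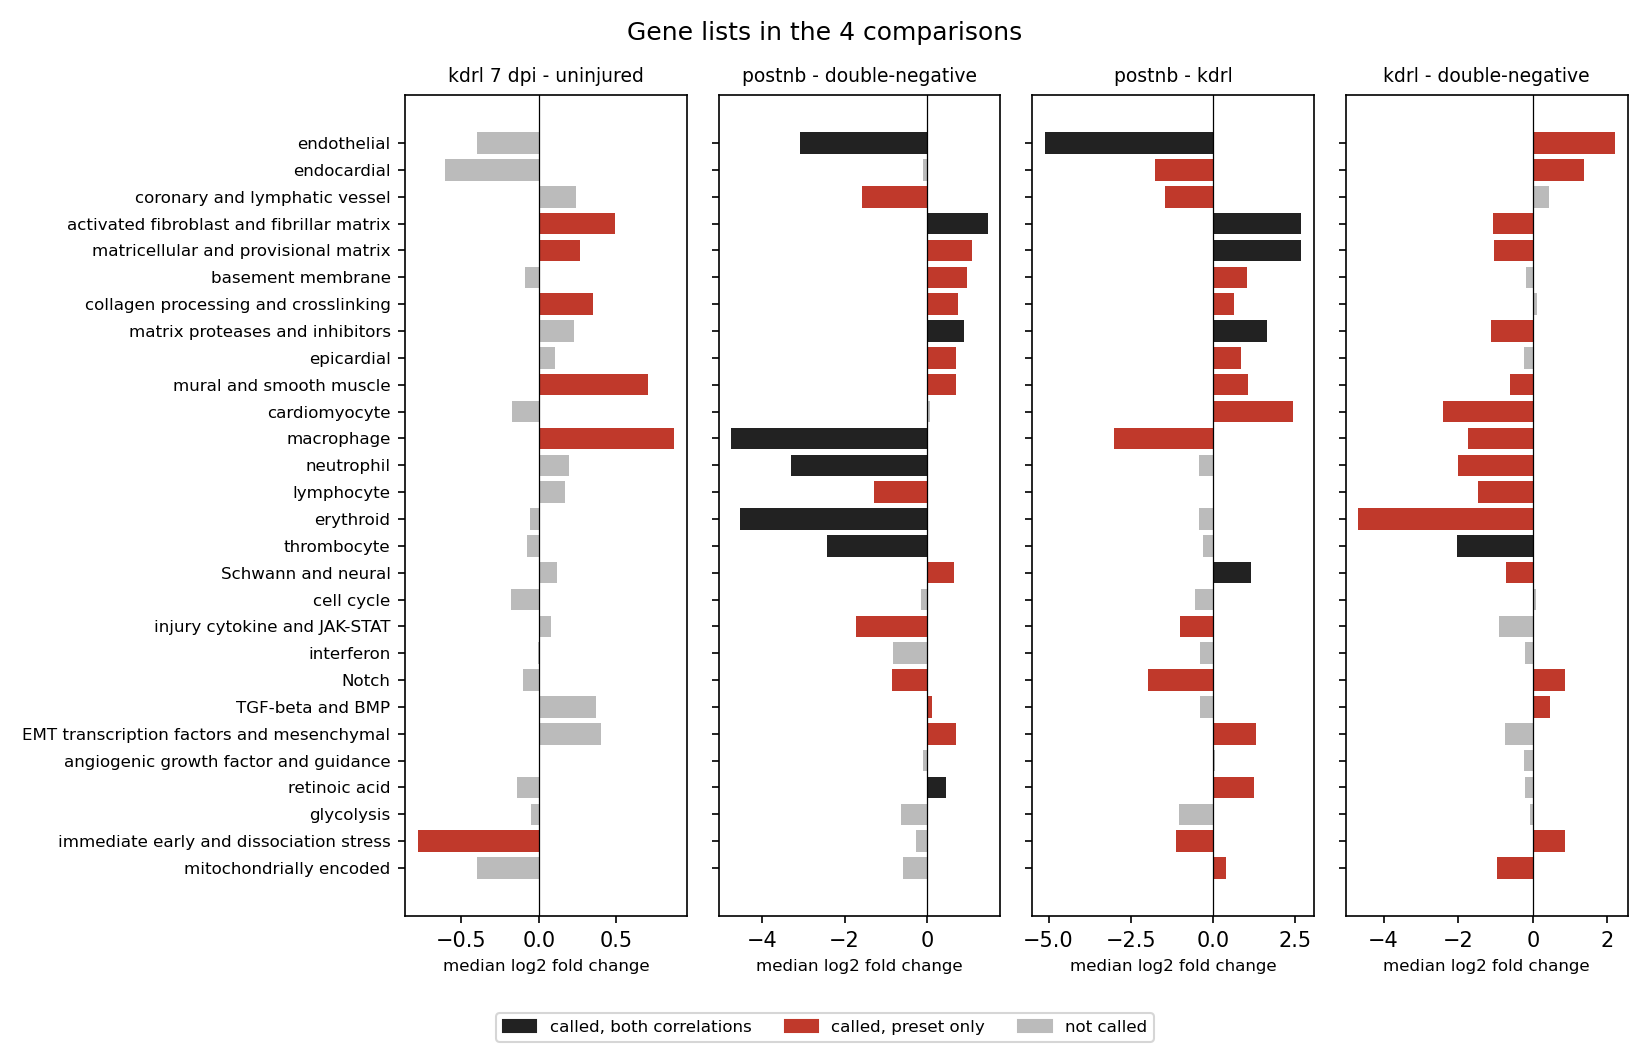
Median log2 fold change of the measured members of each of the 28 gene lists in the 4 comparisons, on horizontal axes of different scale; black bars passed with the preset and the estimated correlation, red bars with the preset one alone, and grey bars did not pass. No bar is black in the comparison with uninjured hearts, where macrophage genes had a median of 0.87.

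Lists of cell cycle, interferon, glycolysis, and angiogenic growth factor and guidance genes passed in none of the 4 comparisons over all libraries. For cell cycle genes camera gave adjusted p = 0.837, 0.939, 0.474 and 0.386 in the order of the comparisons above, for interferon genes 0.903, 0.087, 0.474 and 0.379, for glycolysis genes 0.837, 0.249, 0.666 and 0.613, and for angiogenic genes 0.958, 0.871, 0.474 and 0.357. In the angiogenic list of citrine-positive against double-negative cells, CXCR4 and dll4 were among 9 lower members and 5 others were higher, with a median of -0.09, a mean of -0.52 and a test direction upward. Median, mean and test also differed in sign, with no call, for thrombocyte, Schwann and neural, interferon, angiogenic and glycolysis genes at 7 dpi against uninjured, for thrombocyte and angiogenic genes in citrine-positive against mCherry-positive cells, and for coronary and collagen processing genes in mCherry-positive against double-negative cells.

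The last comparison asked whether genes raised with injury in mCherry-positive cells were those enriched in citrine-positive cells. Both lists shared 5 genes (CLU, COL5A1, FN1, DKK3 and TGM2), against 1.42 by independent lists (Fisher's exact test, one-sided, p = 0.0139). CLU (ENSDARG00000010434) and DKK3 (ENSDARG00000070683), named after their values were seen, had 21.1 ± 5.61 and 9.44 ± 4.07 TPM in mCherry-positive libraries at 7 dpi. Lower in both were 4 genes, against 4.2 (Fisher's exact p = 0.614). Of the genes raised with injury 20 were lower in citrine-positive than double-negative cells, against 6.46 (Fisher's exact p = 3.94e-06), NPC2, F13A1, MFAP4 and ccl35.1 among them. The compared groups shared no library, but pools 5, 6, 7 and 9 gave libraries to both comparisons. Both lists of calls also rest on a spread per gene estimated over all groups, here and in the settings that follow. A gene with a small spread is more easily called in both, so the lists were not independent and Fisher's p can overstate the overlap. Without pools 7 and 9 in the injury comparison 6 genes were shared (expected 4.56, Fisher's exact p = 0.307). With double-negative pools 5 and 6 also left out, so that no pool number was in both, a setting chosen after the data were seen, it was 6 (expected 2.85, Fisher's exact p = 0.067). Without mCherry-positive pool 9 at 7 dpi it was 5 (expected 1.86, Fisher's exact p = 0.0393), and after median-of-ratios scaling 22 (expected 6.27, Fisher's exact p = 2.64e-07), both also chosen after the data were seen. Across genes, which are not independent replicates, the fold changes had a Pearson r of -0.10, and 9 of 35 splits of the 7 mCherry-positive libraries gave an r as far from 0 (exact two-sided p = 0.257).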

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

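The tests on carry-over, macrophages, sets of pools and pool 7 were chosen after the result was seen, and those on other groupings of the libraries before. The carry-over test was revised once, and the pool 7 tests once, after their values were seen.

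In groups of 4 or 6 libraries, 1 lay far from the others in 19 of 163 combinations of group and gene or library measure. The rule was Dixon's ratio, the gap to the nearest library over the range. Its cutoffs flag about 5% of independent normal values. TPM can be skewed and related genes vary together, so 5% is not the chance rate here. A gene at 0 in all other libraries is flagged at any value, as were TNC, plp1b, TCF21 and ADAMTS8. Of the 19, 6 were in the mCherry-positive library of pool 9 at 7 dpi and 5 in that of pool 7. The double-negative libraries of pools 6 and 7 had 3 each and those of pools 5 and 9 had 1 each. In mCherry-positive pool 9 these were COL1A2 at 359.6 TPM (nearest other library 118.9), POSTN (ENSDARG00000043806) at 407 (97.1), MMP2 at 35.07 (16.8), smtnb at 40.3 (149.8), TNC at 0.91 and plp1b at 0.38, both 0 elsewhere. In mCherry-positive pool 7 they were tfa at 16.4 TPM (2.1), hbaa2 at 27.3 (1.90), MMP9 at 2.14 (0.57), TCF21 at 0.53 and ADAMTS8 at 0.30, both 0 elsewhere. In double-negative pool 7, hbaa1 was at 20600 TPM (7314), hbaa2 at 4228 (1586) and alas2 at 831.1 (279.2). In double-negative pool 6, COL12A1 was at 114 TPM (65.9), abi3bpb at 15.6 (9.50) and RSPO1 at 0.57 (0.09). MMP15 was at 9.48 TPM in double-negative pool 9 (5.61) and CYP26B1 at 4.63 in pool 5 (13.8).

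Of the matrix lists, 6 genes rose in mCherry-positive cells at 7 dpi, and no matrix list held with an estimated correlation (adjusted p = 0.758 for the 3 called). If cells of the citrine-positive kind had entered the sort, the 5 genes other than FN1 would need, as a median per library, between 7.27% and 46% of their citrine-positive level (single genes 5.23% to 182%). The upper quartile of 18 abundant citrine-positive transcripts was 2.67% to 11% and lay below 5 of 5 genes in 4 of 4 libraries. The 18 included cmlc1 of the cardiomyocyte list, at 832.4 TPM in citrine-positive pool 7 against a mean of 47.44 in pools 9 and 10. They also included CLU and TGM2, themselves called higher at 7 dpi. The 5 genes were picked for their rise in these libraries, unlike the 18 transcripts as a set. A higher share was thus partly fixed by the choice, and the comparison does not decide whether such cells were the source. For FN1 the share lay above the quartile in 2 of 4 libraries, so FN1 from such cells cannot be told apart from FN1 of the sorted cells. With pools 2 to 8 alone the median log2 fold change of the 6 matrix genes was 2.44, against 2.63 with all pools. It was 2.15 to 3.05 over the 3 libraries, and 2 of the 6 kept their call. The rise was thus not confined to the other set of pools. The 6 genes were picked for their rise in a fit that included these 3 libraries, so a positive median was partly fixed by the choice. The comparison does not decide whether the set of pools added to the rise. A response of mCherry-positive cells to injury stays a hypothesis. Cells of the citrine-positive kind were not excluded, and free RNA in the dissociated tissue was not tested. Differences between pools also cannot be told apart from injury.

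Of 30 macrophage genes 2 rose in the same comparison, and the list had adjusted p = 0.758 with an estimated correlation. The gain of apoeb was 162% to 415% of its level in the double-negative mixture, which is not a share of cells. The upper quartile of 12 abundant macrophage transcripts on the same scale was at most 45.6% and lay lower in 4 of 4 libraries. As apoeb was picked for its rise and the 12 were members not called, a larger gain was partly fixed by the choice. The comparison does not decide whether macrophages were the source. For MFAP4 the gain lay above that quartile in 3 of 4 libraries, and more macrophages in the sort at 7 dpi cannot be told apart from a change within the sorted cells. Macrophages of another state than those of the double-negative sort were not tested.

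Cardiomyocyte genes were higher in citrine-positive than mCherry-positive cells with the preset correlation (adjusted p = 0.200 with an estimated correlation). Of 15 called members 8 were still called higher without citrine-positive pool 7, so that library alone does not account for those. By chance 1.44 of 30 tested would be expected (exact one-sided hypergeometric p = 6.32e-05). That p treats the genes as independent, although their estimated correlation was 0.507, so it overstates the evidence. The other 7 had a median log2 fold change of 3.09 with all libraries and 1.81 without it (1.31 to 2.41), so part of their rise came from it and the rest cannot be decided from 2 libraries. The double-negative library of pool 7 ranked 2 of 6 for these genes (85.8 TPM, range 43.8 to 108.8), so more muscle RNA in the hearts of pool 7 stays open. No biological explanation was tested.

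In all 4 comparisons the real grouping gave more calls than every other split tried. With 35 splits a rank of 1 is the strongest result possible, so chance is not excluded there. For 7 dpi against uninjured, groups also did not overlap for 6.92% of genes, against 5.71% by chance. The real grouping gave the most calls in 1 of 35 splits for 7 dpi against uninjured (132, highest other 92), 1 of 84 for citrine-positive against double-negative (1876, 16), 1 of 35 for citrine-positive against mCherry-positive (2268, 1765) and 1 of 100 drawn splits for mCherry-positive against double-negative cells (2083, 111). The split with 1765 calls put mCherry-positive pool 9 with the citrine-positive libraries.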

How the results depend on the processing

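Array weights, removal of abundant IDs, quantile normalization and the fits by set of pools, and for the overlap the setting with no pool in both, the one without mCherry-positive pool 9 and median-of-ratios scaling, were chosen after the result was seen, the others before. Planned for counts and not run on TPM were the DESeq2 Wald test and voomWithQualityWeights. The cause of each change below was not tested, except that fits within sets of pools and without a library have fewer libraries. The citrine-positive arm within pools 2 to 8 (pool 7) and the mCherry-positive arm within pools 9 and 10 (pool 9) were 1 library each, assumed to vary like the other groups.

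For 7 dpi against uninjured, limma called 132 genes. It called 0 on the 2 groups alone (1306 at an unadjusted p under 0.05), 86 with a pseudocount of 5 (32 higher, 54 lower), 53 with array weights, 228 without the 20 most abundant IDs (81.6% higher against 60.6%), 324 with the set of pools as a term, and between 83 and 205 leaving out 1 library. Of 28 lists 6 were called, 0 with an estimated correlation, 11 with the set of pools as a term and 10 within pools 2 to 8 (the 6 among both the 11 and the 10), and between 5 and 8 leaving out 1 library.

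For citrine-positive against double-negative cells (1876 genes) the count was 3577 with array weights, 2830 after quantile normalization (46.5% higher against 18.0%), 896 within pools 2 to 8, 803 within pools 9 and 10, 1301 with the replicate block of pools, and between 1285 and 1905 leaving out 1 library. Of 28 lists 20 were called, 8 with an estimated correlation, and between 18 and 22 leaving out 1 library (22 without citrine-positive pool 7, 19 of them among the 20). Glycolysis turned upward within pools 2 to 8, on 1 citrine-positive library (0.12, adjusted p = 0.0128), and cardiomyocyte genes downward without citrine-positive pool 7 (-1.07, adjusted p = 0.0012), against 0.73 at most without another library.

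For citrine-positive against mCherry-positive cells (2268) it was 1082 on the 2 groups alone, 1510 within pools 2 to 8, 418 within pools 9 and 10, 1444 with the replicate block, and between 1712 and 2657 leaving out 1 library. Quantile normalization gave 53.3% and removal of the 20 most abundant IDs 54.3% of calls higher, against 40.7%. Of 28 lists 19 were called, 5 with an estimated correlation, and between 18 and 20 leaving out 1 library (20 without citrine-positive pool 7, 18 of them among the 19). Within pools 2 to 8 glycolysis had a median of -0.046 (adjusted p = 0.0305, test upward), and within pools 9 and 10 TNNT2 was at -0.40 (adjusted p = 0.389).

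For mCherry-positive against double-negative cells (2083) it was 2 within pools 9 and 10 (0 higher), 1664 with the replicate block, and between 1472 and 2508 leaving out 1 library. Of 28 lists 17 were called, 1 with an estimated correlation, and between 15 and 17 leaving out 1 library. Where it was run, the block changed no other call than those named beside the results. It was not possible for the comparison with uninjured hearts.

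The overlap of injury-raised with citrine-enriched genes was, with Fisher's exact test, 6 without pools 7 and 9 (p = 0.307), 6 with no pool in both (p = 0.067), 7 with the stricter filter (p = 0.00103) and 22 after median-of-ratios scaling (p = 2.64e-07). On the 2 groups alone it was 0 by construction, since no gene was called for injury there, so it says nothing of the overlap. Leaving out 1 library, 10 of 27 named calls held throughout for 7 dpi against uninjured, 41 of 45 and 32 of 33 for citrine-positive against double-negative and mCherry-positive cells, and 29 of 32 for mCherry-positive against double-negative cells. Unknown depth limits how far low genes can be compared.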

Other observations

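No test was planned for the levels below. The fixed rule for named genes took MYL7, mb and hsp70l in at least 1 comparison, while cd74a and egr1, and the groups and pools set side by side, were chosen after their values were seen.

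Myoglobin RNA was most abundant in the endothelial sort. The gene mb (ENSDARG00000031952) had 11073 ± 1335 TPM in uninjured mCherry-positive libraries, 6270.2 ± 1684 in those at 7 dpi, 1091 ± 252 in double-negative and 450.3 ± 479.9 in citrine-positive libraries, while MYL7 had 44.0 ± 21.6 TPM in mCherry-positive libraries at 7 dpi and 333 ± 123 in double-negative ones. The antigen presentation gene cd74a had 376 ± 319 TPM in uninjured mCherry-positive and 1828 ± 686 in double-negative libraries.

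The heat shock gene hsp70l had between 5844 and 9003 TPM in uninjured mCherry-positive libraries, between 8562 and 10941.3 TPM in the mCherry-positive libraries of pools 5 to 7 at 7 dpi and 120.5 in that of pool 9. It had between 620.0 and 2345 TPM in the double-negative libraries of pools 5 to 8 and 85.4 and 56.2 in those of pools 9 and 10. Citrine-positive libraries had 136.9 TPM in pool 7, 38.2 in pool 9 and 1.38 in pool 10. The immediate early gene egr1 had 715 ± 110.1 TPM in uninjured and 228 ± 65.4 in mCherry-positive libraries at 7 dpi. Of its list, 0 of 37 members passed in that comparison, so egr1 was not called.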
